A study of Mus musculus with 13 samples.

How the data were processed

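Polyadenylated RNA was enriched from total RNA of mouse right ventricles, and stranded Illumina libraries were made, per the labels' protocols. The submitters' processing notes name DRAGEN and the mouse build GRCm39 (mm39), with no version and no order of steps; the annotation used for counting and the strand setting are not given in the sources used here. For each library the authors deposited a gene table with estimated counts of reads per gene, which need not be whole, together with TPM and an effective length, per the file headers. Every table lists the same 26264 gene symbols. Genes encoded in the mitochondrial genome were not analysed here. Groups and replicate numbers were taken from the titles in the labels: 6 wild-type and 7 Dsg2 F536C knock-in libraries.

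The estimated counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr, libraries were scaled by TMM, and knock-in was compared with wild type by the quasi-likelihood F test with robust dispersion (edgeR 4.0.16, R 4.3.3) with no covariate and Benjamini-Hochberg adjustment over all tested genes; calls have an adjusted p under 0.05. CPM values in the text are read numbers per library total after TMM scaling, except the per-library values of keratins, epithelial markers and adipocyte markers, which were scaled by library totals without TMM factors. Log2 CPM used a prior count of 2. SE values of log2 fold changes are the size of the fold change divided by the square root of F. The test, samples, lists and the rule for named genes were fixed before the data were examined.

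The rule names Dsg2, Pparg and Ppara; the 6 largest rises and 6 largest falls among called protein-coding genes with a mean of at least 1 CPM and no overlap between the groups; and, by smallest p, 3 members of each main list with at least 3 called members and 2 members of each cell type or quality list with at least 2. Applying the fold rule to the 10 libraries as well was decided after seeing the data. Some genes that the rule names are not reported here. The 40 lists are 18 main lists, 18 cell type lists and 4 quality lists. Members were matched by symbol or by a synonym in a RefSeq gene table. Lists with at least 5 tested members were tested with camera (limma 3.58.1), with a preset inter-gene correlation of 0.01 and with the correlation estimated per list, and with fry, which does not compare a list with other genes. Adjustment was made over the main lists and over the others separately. The mitochondrially encoded list had no member to test and the thymus and lung list too few.

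A library was set apart where the share of values that were not whole, with a tolerance of 1e-09, was over 2 times the median share, which held for knock-in 4, 5 and 6. The exons that overlap on opposite strands by at least 50 bases were taken from a GENCODE annotation of an older build, GRCm38, for the relation between neighbouring genes only, and 24964 of the symbols matched it. No coordinates are given. Opposite-strand partners and close paralogs or pseudogenes may share reads in these tables, so values of such genes are uncertain, most of all in knock-in 4, 5 and 6.

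Differences of single values between groups were tested by exact permutation of the group labels, two-sided, over every split of the libraries into groups of the same sizes. The smallest p these can give is 0.000583 with 13 libraries and 0.00476 with 10. Scores for correlations were means of gene-wise z values within a group, with exact permutation of the pairings. Random regroupings of the libraries were limited to 100 for each set, the real one included. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for these tests.

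The pipeline was tested on simulated counts drawn from the wild-type means, the library sizes and the dispersions, with 200 changed genes and a further list of genes shifted upward. Genes were drawn independently, few were changed and no library was set apart, so the rates below need not hold for the real data. With the 13 libraries, 57.3% of 2-fold and 11.0% of 1.5-fold changes were recovered among 14195 genes, and 6.85% of calls were false. With the 10 libraries these were 83.0%, 46.5% and 4.79% among 14216 genes. The common dispersion was 0.0974 with 13 libraries and 0.0276 with 10. Totals were 14498336 to 29848597 reads per library.

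Alternatives fixed before the data were examined were DESeq2 size factors, library totals, DESeq2 (1.42.0), limma-voom with quality weights, other filters, limma on log2(TPM + 1) and log2(TPM + 0.1), effective length offsets, a replicate block, Xist as a covariate, 1 surrogate variable (sva 3.50.0), haemoglobin genes left out, stricter thresholds and each library left out in turn. Those added later were the 10 libraries without knock-in 4, 5 and 6, an indicator for these 3, and leaving out genes that overlap the opposite strand.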

Results

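Right ventricles of wild-type mice and of mice carrying the F536C substitution in Dsg2 were compared by RNA sequencing of polyadenylated RNA. Dsg2 encodes desmoglein 2, a cadherin of the desmosomes that join cardiomyocytes, and the series asks how PPAR-gamma signalling relates to fibrosis, lipid accumulation and arrhythmia in this model of arrhythmogenic cardiomyopathy. There were 6 wild-type and 7 knock-in libraries, with estimated read numbers for 26264 genes and totals from 14498336 to 29848597 reads per library. The labels give no sex, age, litter or batch and do not say that each library came from a separate animal, so p-values measure the spread between these samples. Every pair of libraries within a group differed by more than sampling noise: the closest pair, wild type 3 and 6, had a chi-square of 7.52 per degree of freedom.

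Knock-in 4, 5 and 6 stood apart from the other 10 libraries in how their values were made and in what they held. Between 10.2% and 10.7% of their read numbers were not whole, against 3.07% to 3.79% in the other 10. Among genes with an exon overlapping an exon on the opposite strand, 48.4% to 50.5% of values above 10 reads were not whole, against 2.31% to 2.84%. Their log2 CPM correlated with those of the other knock-in libraries at r of 0.897 to 0.924 across genes, which are not independent replicates. The other 4 knock-in libraries correlated with the wild-type ones at 0.940 to 0.972. Keratins of epithelia were far higher in these 3 libraries: Krt8 lay between 969.5 and 1214 CPM, and at most at 7.23 CPM in any other library, and Krt19 between 523 and 1404 CPM against at most 15.97. All wild-type libraries belonged with the other 10, so the genotypes could not be compared among these 3. Results are therefore given for all 13 libraries and again for the 10 libraries without knock-in 4, 5 and 6, a choice made after seeing the data. Where a pair of values is given, the first is for 13 libraries and the second for 10.

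**Figure D1:**
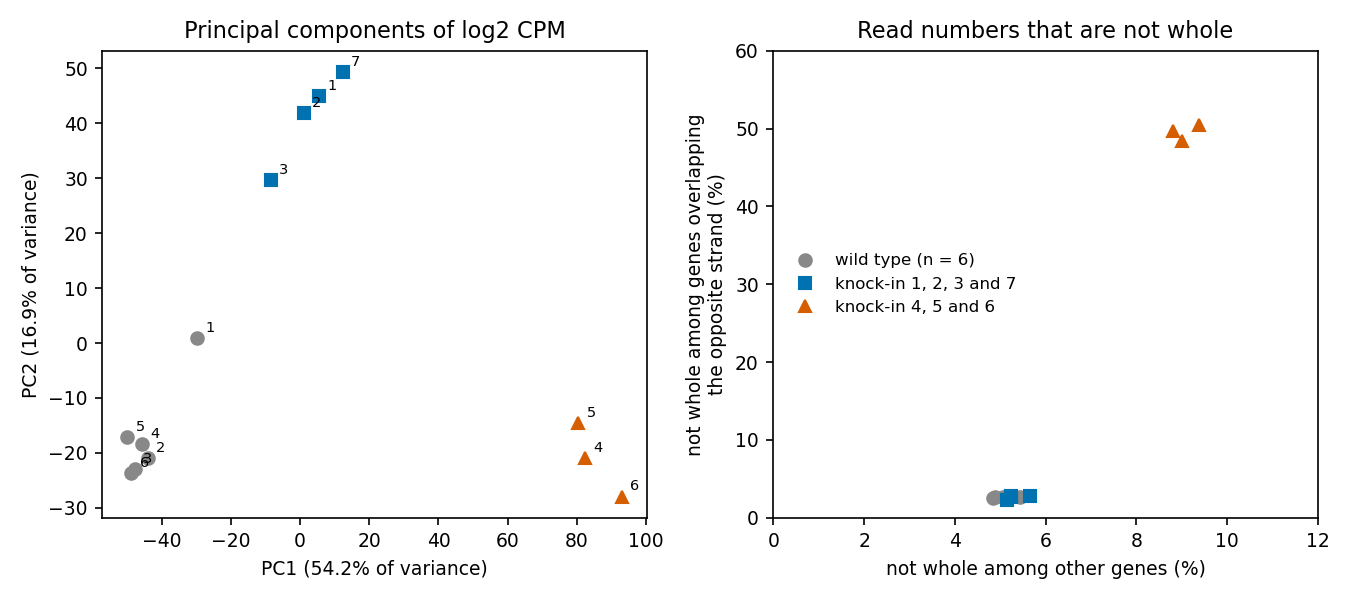
Left, the first and second principal components of log2 CPM for the 13 libraries, numbered by replicate, with 54.2% and 16.9% of the variance. Right, the percentage of values above 10 reads that were not whole among genes overlapping the opposite strand against that among other genes; knock-in 4, 5 and 6 lie above 48% and the other 10 libraries at 2.84% or less.

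Dsg2 was lower in every knock-in library than in any wild-type library, going from 101 ± 11.2 to 47.7 ± 10.3 CPM (SD, n = 6 and 7). The log2 fold change was -1.08 ± 0.14 (SE, adjusted p = 6.96e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and -0.97 ± 0.12 (SE, adjusted p = 3.16e-05) with the 10 libraries. The read numbers do not show the substitution itself. Pparg, which encodes the nuclear receptor PPAR-gamma, did not pass the test: its levels were 14.7 ± 3.40 CPM in wild type and 17.9 ± 8.96 CPM in knock-in, a log2 difference of 0.27 ± 0.26 (SE, adjusted p = 0.398), and of 0.51 ± 0.27 (SE, adjusted p = 0.152) with the 10 libraries. Without knock-in 2, which had 37.7 CPM, the log2 differences were -0.02 (adjusted p = 0.923) and 0.06 (adjusted p = 0.796). Pparg passed with limma on log2(TPM + 1) (adjusted p = 0.0419) and log2(TPM + 0.1) (adjusted p = 0.0369) and, with 10 libraries, with library totals (adjusted p = 0.0438) and with Xist as a covariate (adjusted p = 0.0432). Ppara, the receptor that drives genes of fatty acid oxidation in the heart, fell from 80.2 ± 18.4 to 44.6 ± 15.9 CPM, a log2 fold change of -0.85 ± 0.22 (SE, adjusted p = 0.00717). That call was lost with log2(TPM + 1) (adjusted p = 0.0809) and log2(TPM + 0.1) (adjusted p = 0.0754). With the 10 libraries it was -0.54 ± 0.17 (SE, adjusted p = 0.0232), a call lost without knock-in 1 (adjusted p = 0.0744), without knock-in 7 (adjusted p = 0.0761) and with library totals in place of TMM (adjusted p = 0.157).

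Across the transcriptome, 6502 of 14588 tested genes passed an adjusted p of 0.05, 3442 higher and 3060 lower in knock-in. The 10 libraries gave 6340 of 14518, with 3241 higher and 3099 lower. Of the 14441 genes tested in both sets, 2373 were higher in both, 2432 were lower in both, 5 were called in opposite directions, 1616 were called only with 13 libraries and 1509 only with 10. A change of at least 2-fold was seen in 1484 higher and 622 lower genes with all 13 libraries, and in 836 higher and 400 lower genes with 10. The balance of directions depended on the scaling. With library totals in place of TMM factors the 13 libraries gave 6110 higher and 1661 lower genes and the 10 libraries 6049 higher and 1528 lower. The median log2 fold change of all tested genes moved from 0.08 to 0.33 and, with 10 libraries, from 0.02 to 0.26. The 20 most abundant genes took 15.6% ± 1.06 (SD, n = 6) of wild-type reads and 9.83% ± 1.49 (SD, n = 7) of knock-in reads (exact permutation test, two-sided, p = 0.000583, the smallest this test can give), and 10.8% ± 1.03 (SD, n = 4) in the 4 other knock-in libraries (exact permutation p = 0.00476, again the smallest possible).

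The largest rises with all 13 libraries, among protein-coding genes whose groups did not overlap, were those of Crabp2, Aqp5, Col11a1, Spp1, Col9a2 and Tnc, with log2 fold changes of 9.34, 8.15, 7.00, 6.99, 6.80 and 6.78. With the 10 libraries Crabp2 rose by 4.32, Col11a1 by 2.57, Col9a2 by 2.76 and Tnc, the matrix protein tenascin C, by 3.25, and Aqp5 did not pass the filter on low counts. The rises of Crabp2, Aqp5, Col11a1, Col9a2 and Tnc rest largely on knock-in 4, 5 and 6: with 13 libraries Tnc was at 4.27 and Col11a1 at 6.12 without knock-in 4, Crabp2 at 8.32 without knock-in 5 and Col9a2 at 4.53 without knock-in 6. Aqp5 did not pass the filter without knock-in 1, 3, 4, 5, 6 or 7. With an indicator for knock-in 4, 5 and 6 the calls of Aqp5 (adjusted p = 0.104) and Col9a2 (adjusted p = 0.0705) were lost. Aqp5 also lost its call with 1 surrogate variable (adjusted p = 0.0709) and with log2(TPM + 1) (adjusted p = 0.0545), as did Col11a1 with log2(TPM + 1) (adjusted p = 0.0523). Spp1, which encodes osteopontin, a secreted phosphoprotein, rose from 1.23 ± 0.422 to 155 ± 166 CPM (adjusted p = 1.59e-05), and by 7.34 ± 0.75 (log2, SE, adjusted p = 0.000120) with the 10 libraries. Among the other largest rises with the 10 libraries were those of the macrophage elastase Mmp12 (6.27), the proton pump subunit Atp6v0d2 (5.95), the glycoprotein Gpnmb (5.54) and Sprr1a (5.52). They were also called with 13 libraries, at 5.67, 5.40, 5.10 and 5.32. The size of the rises of Spp1 and of 3 of these genes rests on knock-in 7, in which Spp1 was at 524 CPM, against 70.1 to 98.7 CPM in the other 3 knock-in libraries of the 10. Without it, Spp1, Mmp12, Atp6v0d2 and Gpnmb were at 6.26, 4.36, 4.52 and 4.20 (log2) with 13 libraries and at 6.19, 4.61, 4.83 and 4.19 with 10, and all 4 kept their calls. The largest falls with all 13 libraries included those of Sertm1 (-3.39), Pfkfb1 (-2.93), the chloride channel Clcn1 (-2.84), the water channel Aqp4 (-2.81) and the carboxylesterase Ces1d (-2.81). The 10 libraries gave -2.80, -2.73, -3.05, -2.50 and -2.49 for these genes, and placed Pcp4 (-3.53) and the chemokine Ccl11 (-2.73) among their 6 largest falls.

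**Figure D2:**
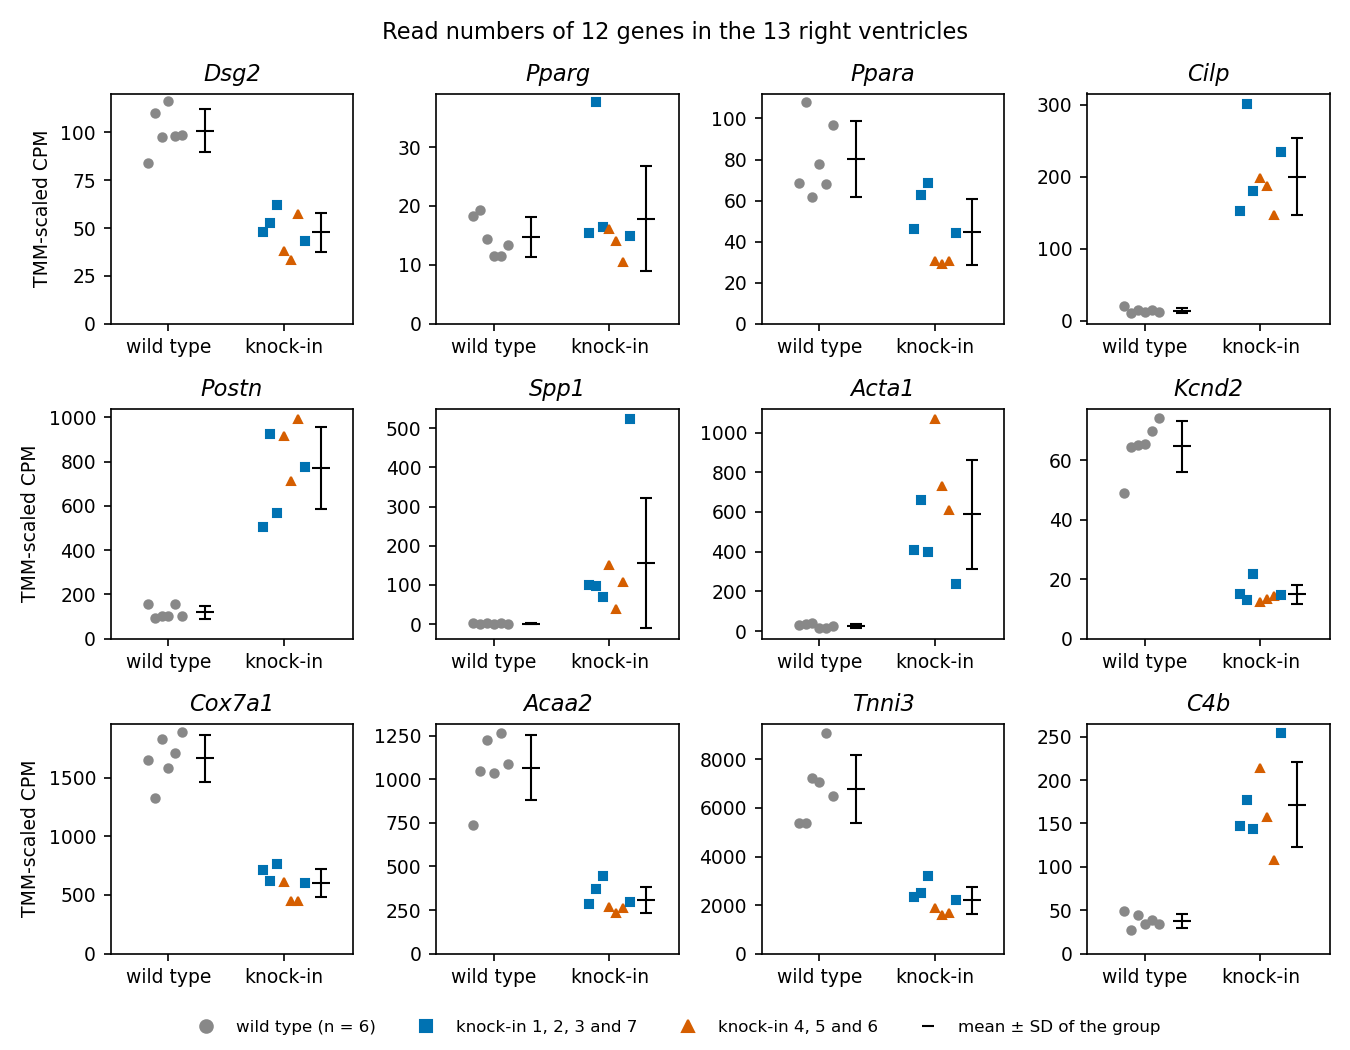
TMM-scaled CPM of 12 genes in each library, with the group mean and SD beside the points. Dsg2, Kcnd2, Cox7a1, Acaa2 and Tnni3 are lower and Cilp, Postn, Spp1, Acta1 and C4b higher in all 7 knock-in libraries than in any wild-type library, while Pparg and Ppara overlap between the groups.

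Genes of the fibrillar matrix and its remodelling rose almost as a whole: 40 of 44 members rose and 0 fell with 13 libraries (41 higher and 0 lower adjusted over the list alone), and 42 rose and 0 fell with 10. The median log2 fold change was 1.85 and 1.39. Col8a1, a short-chain collagen, rose from 23.6 ± 1.58 to 138 ± 27.2 CPM (log2 fold change 2.55 ± 0.13 SE, adjusted p = 1.11e-07). Cilp, a matrix protein, rose from 14.3 ± 3.74 to 199.7 ± 53.4 CPM (3.80 ± 0.21 SE, adjusted p = 1.11e-07) and Postn, periostin, from 120.1 ± 29.3 to 772 ± 187 CPM (2.68 ± 0.20 SE, adjusted p = 1.57e-06). The 10 libraries gave 2.60, 3.92 and 2.53 for these genes. The list test passed with the preset correlation (camera, adjusted p = 9.05e-33 and 8.84e-44) and with an estimated one (adjusted p = 0.00301 and 0.0478 with an estimated correlation). Of the TGF-beta pathway and myofibroblast list, 22 of 34 members rose and 2 fell with 13 libraries (24 higher and 2 lower adjusted over the list alone), and 24 rose and 3 fell with 10. Its test passed too (adjusted p = 6.55e-11 and 3.56e-12; adjusted p = 0.00301 and 0.0478 with an estimated correlation). Ltbp2, a latent TGF-beta binding protein, had log2 fold changes of 3.84 and 4.04, the TGF-beta target Pmepa1 1.56 and 1.43 and the ligand Tgfb3 1.57 and 1.64. Of the fibroblast markers, 4 of 15 members rose and 2 fell with 13 libraries (5 higher and 2 lower adjusted over the list alone), and 8 rose and 1 fell with 10. With library totals 8 rose and 1 fell with 13 libraries, and 10 rose and 1 fell with 10. Mfap5 was at 1.43 and 1.69 and Scara5 at -1.27 and -1.15, and the fibroblast list was called only with 10 libraries (adjusted p = 0.457 and 0.0109; adjusted p = 0.971 and 0.440 with an estimated correlation).

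These were the only 2 of 18 main lists called with an estimated correlation, in either set of libraries, whereas 16 were called with the preset one. The preset call by itself is weak evidence here, since 99 random regroupings of the libraries called a median of 10 main lists with 13 libraries and 11 with 10, and no gene passed the threshold in 97 and 96 of them. Regroupings with unlike shares of knock-in libraries carry part of the genotype contrast. Mixed ones still called lists: 2 to 15 where 4 of the 7 knock-in libraries were in the larger group, and 2 to 16 where 2 of the 4 were in the smaller group of the 10 libraries.

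Genes of mitochondrial energy metabolism were lower. In the oxidative phosphorylation list, nuclear genes of the respiratory chain and ATP synthase, 0 of 39 members rose and 39 fell with 13 libraries (0 higher and 39 lower adjusted over the list alone), and 0 rose and 39 fell with 10. Cox7a1, a cytochrome c oxidase subunit, fell from 1663 ± 202 to 602 ± 119.9 CPM (adjusted p = 1.02e-05), with log2 fold changes of -1.47 and -1.30. The complex I subunits Ndufs7 and Ndufs1 were at -1.04 and -0.89, and at -1.25 and -1.13. The preset test (adjusted p = 8.63e-33 and 8.11e-24) was lost with an estimated correlation (adjusted p = 0.0772 and 0.0901). Of the fatty acid oxidation list, 0 of 33 members rose and 28 fell with 13 libraries (0 higher and 28 lower adjusted over the list alone), and 1 rose and 27 fell with 10. The acyl-CoA thioesterase Acot1 was at -1.96 and -2.13, the thiolase Acaa2 at -1.79 and -1.61 and the dienoyl-CoA isomerase Ech1 at -1.90 and -1.70. That call (adjusted p = 1.62e-24 and 1.05e-16) was lost with an estimated correlation (adjusted p = 0.0772 and 0.0985). With library totals the medians of the oxidative phosphorylation list were -0.86 and -0.67, and those of the fatty acid oxidation list -0.91 and -0.75.

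Genes of lipid uptake and lipid droplets were lower more often than higher: 4 of 28 members rose and 15 fell with 13 libraries (5 higher and 16 lower adjusted over the list alone), and 2 rose and 12 fell with 10. Fitm1, which partitions triglyceride into droplets, was at -1.25 and -1.08, the lipoprotein receptor Vldlr at -1.28 and -1.17 and the droplet coat protein Plin5 at -1.26 and -1.03. The call (adjusted p = 8.52e-05 and 0.00124) was lost with an estimated correlation (adjusted p = 0.145 and 0.165). With library totals in place of TMM 6 rose and 10 fell with 13 libraries, and 5 rose and 7 fell with 10, and the median over 10 libraries moved from -0.34 to -0.09. Of the list of PPAR-gamma and the adipocyte program, 0 of 25 members rose and 3 fell with 13 libraries (0 higher and 3 lower adjusted over the list alone), and 0 rose and 3 fell with 10. The 3 were Dgat2, which completes triglyceride synthesis, at -1.08 and -0.98, the lipoprotein lipase Lpl at -1.45 and -1.18 and the glycerol channel Aqp7 at -0.80 and -0.57. Aqp7 lost its call with limma on log2(TPM + 1) (adjusted p = 0.122) and log2(TPM + 0.1) (adjusted p = 0.119). With 10 libraries it lost it with library totals (adjusted p = 0.119). The list was called with 13 libraries and not with 10 (adjusted p = 0.0455 and 0.323; adjusted p = 0.539 and 0.760 with an estimated correlation). The call with 13 was lost without wild type 1 (adjusted p = 0.317), knock-in 1 (adjusted p = 0.0614), 3 (adjusted p = 0.0810), 4 (adjusted p = 0.0929) or 6 (adjusted p = 0.0916), and with fry (adjusted p = 0.119). Without knock-in 2 the 10 libraries gave a call (adjusted p = 0.0252), and 8 members fell with 13 libraries and 6 with 10. With library totals 1 rose and 3 fell with 13 libraries, and 2 rose and 2 fell with 10. Its median over 10 libraries moved from -0.18 to 0.06. Medians with TMM were -0.445 and -0.337 for the lipid uptake and droplet list and -0.427 and -0.177 for the PPAR-gamma list. The sarcomere list, described below, fell further, with medians of -0.733 and -0.489. A lower share of cardiomyocyte RNA could lower genes of these lists too. It was not tested for them and stays open. Adipocyte markers varied within a group: Adipoq ranged from 6.75 to 70.3 CPM in wild type, and Ucp1 was at 39.1 CPM in knock-in 2 and at most at 2.95 CPM elsewhere.

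Electrical and contractile genes were more often called lower than higher, to an extent that depended on the scaling. Of the ion channel and connexin list, 3 of 38 members rose and 24 fell with 13 libraries (3 higher and 24 lower adjusted over the list alone), and 3 rose and 22 fell with 10. The potassium channel gene Kcnd2 fell from 64.7 ± 8.61 to 14.9 ± 3.19 CPM (adjusted p = 6.23e-07), with log2 fold changes of -2.12 and -2.01. Kcnj3 and Kcnj5, which form the acetylcholine-gated potassium channel, were at -1.82 and -1.74, and at -1.44 and -1.22. The call (adjusted p = 1.42e-09 and 3.58e-07) was lost with an estimated correlation (adjusted p = 0.127 and 0.0901). Of the calcium handling list, 4 of 30 members rose and 16 fell with 13 libraries (4 higher and 16 lower adjusted over the list alone), and 3 rose and 14 fell with 10. The calcium pump gene Atp2a2 fell from 9614 ± 963 to 4019.6 ± 1159 CPM, with log2 fold changes of -1.26 and -1.02; Hrc was at -1.17 and -0.96 and the kinase gene Camk2d at -0.81 and -0.69. That call (adjusted p = 0.000225 and 0.00189) was also lost (adjusted p = 0.127 and 0.165 with an estimated correlation). With library totals 7 rose and 13 fell with 13 libraries, and 8 rose and 11 fell with 10, and the median over 10 libraries moved from -0.33 to -0.09. Of the sarcomere list, 0 of 24 members rose and 17 fell with 13 libraries (0 higher and 18 lower adjusted over the list alone), and 0 rose and 14 fell with 10. Troponin I, Tnni3, was at -1.62 and -1.40, leiomodin 3, Lmod3, at -1.03 and -0.90 and nebulette, Nebl, at -1.14 and -0.91, and the call (adjusted p = 8.76e-09 and 4.27e-05) was lost as well (adjusted p = 0.206 and 0.295 with an estimated correlation). With library totals 1 sarcomere gene rose and 13 fell, and 3 rose and 10 fell with 10 libraries; for ion channels and connexins these were 5 and 20, and 6 and 20. Of the desmosome and intercalated disc list, 2 of 23 members rose and 10 fell with 13 libraries (2 higher and 10 lower adjusted over the list alone), and 2 rose and 10 fell with 10. Besides Dsg2, Gja1, connexin 43, fell from 704 ± 66.1 to 356 ± 87.2 CPM (adjusted p = 0.000175), at -0.98 and -0.88, and the desmosomal cadherin Dsc2 was at -0.99 and -0.96. The list was called (adjusted p = 0.0176 and 0.0103), but not with an estimated correlation (adjusted p = 0.345 and 0.438) nor, with 13 libraries, without wild type 2 (adjusted p = 0.0601). With library totals 4 rose and 6 fell with 13 libraries, and 6 rose and 6 fell with 10. The desmosome median moved from -0.16 to 0.08 over 13 libraries and from -0.25 to 0.00 over 10. Medians with TMM were -0.74 and -0.59 for ion channels and connexins and -0.57 and -0.33 for calcium handling, beside -0.73 and -0.49 for the sarcomere. A lower share of cardiomyocyte RNA could lower all of these lists. It was not tested for them and stays open.

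Of the cardiac stress response list, 16 of 27 members rose and 2 fell with 13 libraries (16 higher and 2 lower adjusted over the list alone), and 18 rose and 2 fell with 10. Gdf15, a stress-induced cytokine, rose from 0.685 ± 0.314 to 11.4 ± 3.24 CPM (adjusted p = 1.67e-06), with log2 fold changes of 4.04 and 4.13, and Acta1, skeletal alpha-actin, from 25.7 ± 9.95 to 588 ± 273 CPM (adjusted p = 4.75e-06), with 4.51 and 4.05. The angiotensin receptor gene Agtr1a fell from 38.2 ± 3.93 to 13.5 ± 2.65 CPM. The call (adjusted p = 8.27e-09 and 1.67e-11) was lost with an estimated correlation (adjusted p = 0.127 and 0.0985).

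In 3 immune lists the genes called were mostly higher. Of the inflammatory cytokine and adhesion list, 21 of 38 members rose and 1 fell with 13 libraries (21 higher and 1 lower adjusted over the list alone), and 20 rose and 2 fell among 36 tested with 10. Scaled by library totals, 28 rose and 1 fell with 13 libraries, and 30 rose and 2 fell with 10. The chemokines Cxcl5 and Ccl8 were at 2.45 and 2.36, and at 2.30 and 2.56, and the myeloid transcription factor gene Spi1 at 1.30 and 0.97. The call (adjusted p = 3.24e-05 and 4.28e-07) was lost with an estimated correlation (adjusted p = 0.127 and 0.128). Of the complement and antigen presentation list, 18 of 24 members rose and 0 fell with 13 libraries (18 higher and 0 lower adjusted over the list alone), and 19 rose and 0 fell with 10. Complement C4b rose from 38.0 ± 8.12 to 172 ± 48.7 CPM, with log2 fold changes of 2.18 and 2.25; C1ra was at 1.01 and 0.97 and C1s1 at 0.68 and 0.76. That call (adjusted p = 5.99e-07 and 5.01e-10) was also lost (adjusted p = 0.145 and 0.159 with an estimated correlation). Of the interferon response list, 5 of 29 members rose and 1 fell with 13 libraries (3 higher and 0 lower adjusted over the list alone), and 19 rose and 0 fell with 10. The antiviral genes Oas3 and Oas1a were at 2.99 and 2.61, and at 0.77 and 1.08, and Mx1, annotated as a transcribed pseudogene, at 1.36 and 1.18. The interferon call (adjusted p = 0.0277 and 4.27e-05) was lost with an estimated correlation (adjusted p = 0.539 and 0.286) and, with 13 libraries, without knock-in 1 (adjusted p = 0.0941), 3 (adjusted p = 0.0506) or 7 (adjusted p = 0.0751), with fry (adjusted p = 0.0553) and with a replicate block (adjusted p = 0.125), where Oas1a lost its call too (adjusted p = 0.0780). With 13 libraries 3 rose without wild type 3, 3 without wild type 6 and 8 without knock-in 2. The count depended on the scaling too, since with library totals 17 rose and 0 fell with 13 libraries, and 26 rose and 0 fell with 10.

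The macrophage, T and NK cell and lymphatic lists were called higher as well, and those of monocytes and neutrophils, B and plasma cells and mast cells were not called. Of the macrophage markers, 12 of 16 members rose and 0 fell with 13 libraries (13 higher and 0 lower adjusted over the list alone), and 14 rose and 0 fell with 10. Gpnmb was at 5.10 and 5.54 and the lipid-sensing receptor Trem2 at 2.06 and 2.36, and the call (adjusted p = 0.00253 and 1.84e-05) was lost with an estimated correlation (adjusted p = 0.749 and 0.415). Of the T and NK cell markers, 5 of 8 members rose and 0 fell with 13 libraries (5 higher and 0 lower adjusted over the list alone), and 3 rose and 0 fell among 6 tested with 10. Scaled by library totals, 6 rose and 0 fell with 13 libraries, and 5 rose and 0 fell with 10. Il7r was at 2.64 and 2.91 and Cd4 at 1.78 and 1.74. That call (adjusted p = 0.0154 and 0.0477; adjusted p = 0.667 and 0.529 with an estimated correlation) was lost with 10 libraries without wild type 2 (adjusted p = 0.0786), wild type 6 (adjusted p = 0.0542) or knock-in 1 (adjusted p = 0.0549), and with Xist as a covariate (adjusted p = 0.0651). Without knock-in 7 the 10 libraries gave 1.70 for Trem2, 2.27 for Il7r and 1.65 for Cd4. Of the lymphatic endothelial markers, 5 of 8 members rose and 1 fell with 13 libraries (6 higher and 1 lower adjusted over the list alone), and 7 rose and 1 fell with 10. The chemokine gene Ccl21a was at 2.09 and 2.44 and the transcription factor gene Prox1 at -1.17 and -0.98. The lymphatic call (adjusted p = 0.0254 and 1.59e-08; adjusted p = 0.846 and 0.152 with an estimated correlation) was lost with 13 libraries without wild type 1 (adjusted p = 0.0520) or knock-in 1 (adjusted p = 0.0520), 2 (adjusted p = 0.0518) or 3 (adjusted p = 0.0648).

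Of the Wnt and Hippo target list, 12 of 26 members rose and 1 fell with 13 libraries (12 higher and 1 lower adjusted over the list alone), and 14 rose and 2 fell among 27 tested with 10. The secreted Wnt modulators Sfrp2 and Sfrp1 were at 3.78 and 3.75, and at 1.70 and 1.75, and Nkd2 at 2.00 and 2.29. The call (adjusted p = 3.24e-05 and 1.89e-06) was lost with an estimated correlation (adjusted p = 0.105 and 0.0901). Of the cell cycle list, 30 of 32 members rose and 1 fell with 13 libraries (30 higher and 1 lower adjusted over the list alone), and 21 rose and 1 fell with 10. The median log2 fold change was 2.08 with knock-in 4, 5 and 6 and 0.79 without them. Ccnb1 was at 2.10 and 1.10, Mcm6 at 1.26 and 0.62 and Cenpf at -2.05 and -2.13. That call (adjusted p = 1.57e-05 and 0.000185) was also lost (adjusted p = 0.421 and 0.332 with an estimated correlation). Of the cell death and p53 target list, 11 of 28 members rose and 3 fell with 13 libraries (11 higher and 3 lower adjusted over the list alone), and 17 rose and 3 fell with 10. Ptgs2 was at 1.12 and 1.06, Phlda3 at 0.87 and 1.12 and Ccng1 at -0.83 and -0.62. That list was called only with 10 libraries (adjusted p = 0.104 and 0.00157; adjusted p = 0.539 and 0.0985 with an estimated correlation), though 13 libraries gave a call without knock-in 5 (adjusted p = 0.0443) or 6 (adjusted p = 0.0416). Of the integrated stress response list, 13 of 25 members rose and 4 fell with 13 libraries (13 higher and 4 lower adjusted over the list alone), and 9 rose and 5 fell with 10, and it was called in neither set (adjusted p = 0.137 and 0.514). Its named members were Vldlr, given above, Cth at -2.05 and -2.21 and Nupr1 at 2.20 and 1.57.

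**Figure D3:**
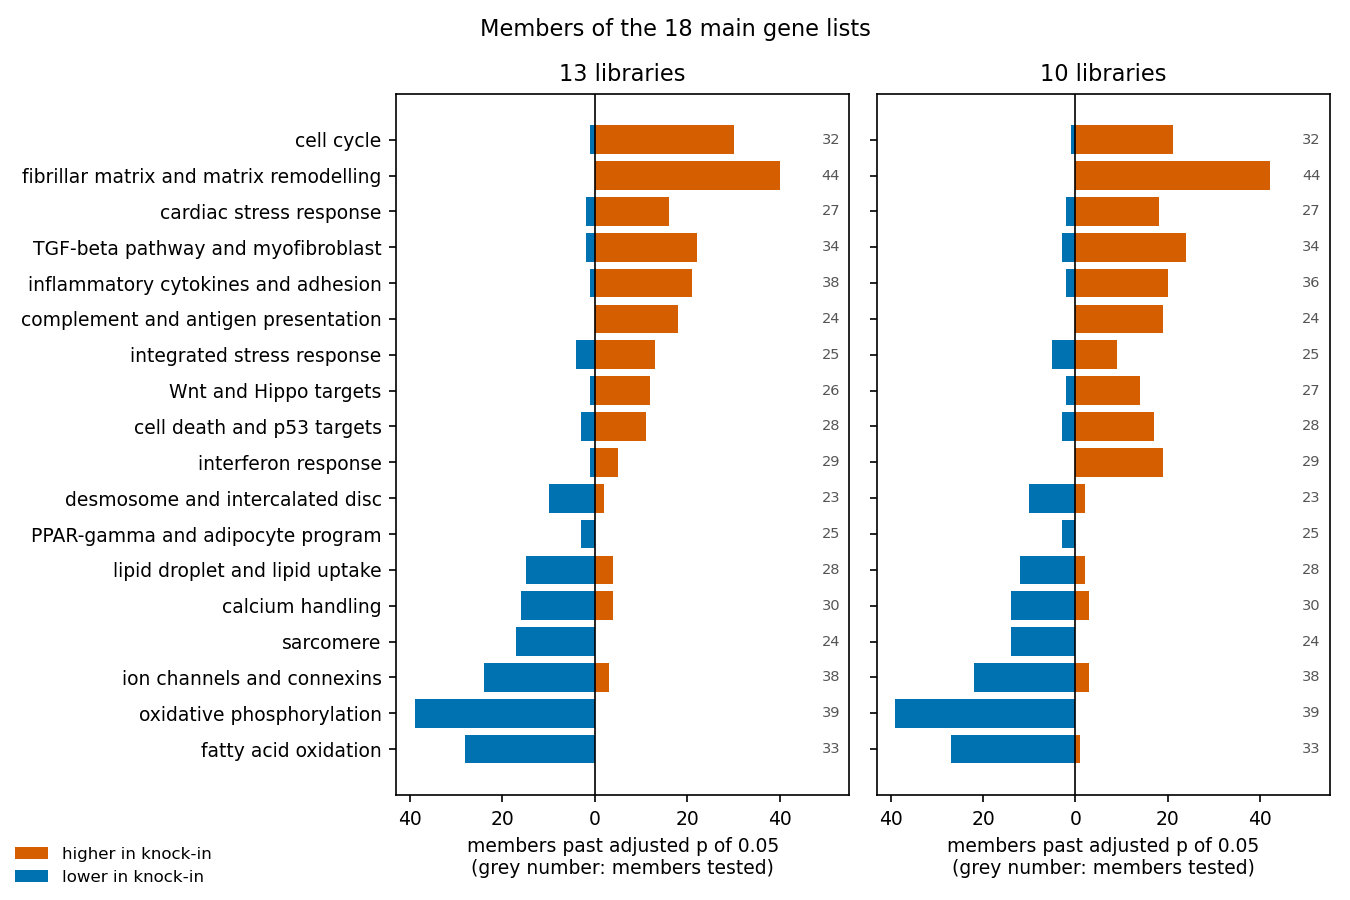
Number of members of each of the 18 main lists past an adjusted p of 0.05, higher (right of 0) or lower (left of 0) in knock-in, for 13 libraries and for the 10 without knock-in 4, 5 and 6, with the number of tested members in grey. All 39 oxidative phosphorylation genes fell in both sets, and 40 and 42 of 44 fibrillar matrix genes rose.

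Knock-in libraries lay farther from their group mean than wild-type ones with all 13 libraries, at a distance of 49.3 ± 9.59 (SD, n = 7) against 26.7 ± 3.62 (SD, n = 6) in log2 CPM over the 1000 most variable genes (exact permutation test, two-sided, p = 0.00117). Within the 10 libraries the distances were 26.9 ± 6.29 (SD, n = 4) and 29.4 ± 3.57 (SD, n = 6), with p = 0.419 in the exact permutation test. Library totals were 19278350 ± 2280234 reads in wild type and 21902557 ± 5285117 in knock-in (exact permutation test, two-sided, p = 0.284; p = 0.895 with 10 libraries). Haemoglobin genes took 0.0815% ± 0.0254 and 0.0852% ± 0.0465 of reads (exact permutation test, two-sided, p = 0.869; p = 0.505 with 10 libraries).

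Relations with the fibrillar matrix score were tested across the 6 wild-type libraries, as 4 of a family of 8 relations. Those across the 7 knock-in libraries entered the correction but are not given, because the libraries fall into separate clusters of 4 and 3. Pearson's r was 0.0863 for Pparg (exact permutation p = 0.882, adjusted p = 0.904), 0.914 for the remaining PPAR-gamma and adipocyte genes (exact permutation p = 0.0167, adjusted p = 0.133), -0.847 for fatty acid oxidation (exact permutation p = 0.0639, adjusted p = 0.256) and 0.715 for macrophage markers (exact permutation p = 0.175, adjusted p = 0.39). Spearman's rho was -0.0286 (exact permutation p = 1.0, adjusted p = 1.0), 0.829 (exact permutation p = 0.0583, adjusted p = 0.467), -0.371 (exact permutation p = 0.497, adjusted p = 0.796) and 0.657 (exact permutation p = 0.175, adjusted p = 0.7). None passed the correction, but with scores taken as the mean of log2 CPM the relation of the PPAR-gamma and adipocyte genes did (r = 0.930, exact permutation p = 0.00278, adjusted p = 0.0222). Without the 2 libraries farthest from the median of the first measure r was -0.138, 0.516, -0.924 and -0.487, each over 4 libraries, too few for a test to pass. The relation of the PPAR-gamma and adipocyte genes may rest on the 2 left out, wild type 1 and 3.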

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

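The tests of strand counting, epithelial RNA, mesothelium and adipose tissue were chosen only after the results were seen. Values of 1 library far from the rest of its group, by the gap to the nearest library relative to the range, were found in 18 of 218 groups examined, where chance gives about 10.9.

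Wild type 1 held 7 of them: Acaa2 at 736 CPM (group median 1067), Dio2 at 10.8 (3.68), Kcnd2 at 48.9 (65.4), Ncam1 at 12.6 (8.46), Sfrp2 at 18.8 (10.2), Tgfb3 at 37.9 (28.9) and Vldlr at 422 (617). In all 7 the library lay on the side of the knock-in mean. Wild type 2 was far from its group in Dgat2, at 273 CPM (median 210.3), and Pcp4, at 1.68 (5.47). Among knock-in libraries, number 7 was far from the rest in 3 macrophage genes: Gpnmb at 401 CPM (median 49.8), Mmp12 at 449 (41.8) and Trem2 at 37.7 (11.97). Knock-in 3 stood apart in Gja1 at 535 CPM (349) and Kcnd2 at 21.8 (14.2), knock-in 4 in Nr2f2 at 87.6 (36.6) and knock-in 5 in Nupr1 at 178 (61.4). Knock-in 2 stood apart in Pparg, at 37.7 CPM against a median of 15.4, and in Tnmd, at 6.99 against 2.69.

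The first pattern is that of knock-in 4, 5 and 6, in which the share of values that were not whole was at least 5.36 times higher in genes overlapping the opposite strand than in other genes, and at most 0.547 times as high in the other 10, which is consistent with reads counted without regard to strand in the 3. That does not account for the 498 genes at least 3 times higher in each of the 3 libraries than in any other, which took 2.19% to 3.02% of their reads: 13.2% of them overlap the opposite strand, against 14.4% of all genes with a mean of at least 1 CPM. Mesothelium is argued against as their main source, since 0% of the 9 measured mesothelial genes other than keratins were 3 times higher there. The median of these 9 was 8.60 CPM in the 3 libraries and 15.25 CPM elsewhere. At that level elsewhere, a small mesothelial part in the 498 genes could stay unseen. RNA of an epithelial tissue may be their source: 85.3% of 34 epithelial genes, 5 of which are in another list and 8 of which reach 1 CPM in wild type, were at least 10 times higher, with a median of 60.4 CPM against 0.146 elsewhere and Krt8 and Krt19 up to 1214 and 1404 CPM, and 0 of the 8 liver, 7 kidney and 6 lung genes were. Whether such RNA came with the pieces, from handling or from another organism was not tested, and because no wild-type library shares the pattern, these explanations and an effect of the genotype cannot be told apart for these 3 libraries; the other 4 knock-in libraries did not show it.

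The second pattern is the variation of adipocyte genes among libraries of one genotype. A candidate explanation is adipose tissue in some of the pieces. The residuals of 16 adipocyte genes, all of them in the fixed PPAR-gamma list and 15 above 1 CPM in wild type, had a mean pairwise correlation of 0.609 across the 10 libraries, where the 99th percentile of 1000 random lists was 0.103. Any set of genes expressed together can exceed random lists, so this value shows that the genes varied together and not why. In wild type 1 Adipoq was at 70.3 CPM, Cfd at 344 and Retn at 32.6, and the atrial genes Myl7 and Sln were highest of the wild types as well, at 341 and 370. In knock-in 2 Ucp1 was at 39.1 and Cidea at 61.0. Pparg, scaled by library totals as well, was high with Adipoq in knock-in 2, at 38.9 and 44.6 CPM. Elsewhere it did not follow Adipoq. Wild type 1 and 2 had Pparg at 18.2 and 18.8 with Adipoq at 70.3 and 7.26. Knock-in 7 and 3 had Pparg at 16.9 and 17.2 with Adipoq at 32.5 and 5.66. Adipocytes formed within the myocardium would give the same correlation and stay open, as no label describes the dissection.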

How the results depend on the processing

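Alternatives with the 10 libraries, the indicator for knock-in 4, 5 and 6 and the genes overlapping the opposite strand left out were added after seeing the data. Of the 108 named genes none changed direction while called, in either set. Of 107 called with 13 libraries, 1, Blk, lost its call when wild type 2, 4, 5 or 6 or knock-in 4 or 5 was left out (adjusted p from 0.0519 to 0.0862), and of 101 called with 10 libraries, 1, Ppara, lost its call without knock-in 1 or 7. With 13 libraries 10 named genes lost a call with log2(TPM + 1), 8 with log2(TPM + 0.1), 7 with the indicator, 6 with 1 surrogate variable and 4 with limma-voom, Krt8 in each of these. Aqp5 and Jchain did not pass the filter in 6 and 5 of the 13 fits without 1 library. Leaving out 1 library gave 5490 to 6830 genes with 13 libraries and 5178 to 6739 with 10. Counts of genes stayed within 1.5 times of the reported ones with DESeq2 (7120), limma-voom (7593), 1 surrogate variable (4987), the indicator (5382), opposite-strand genes left out (5631) and Xist (6622). With library totals the total over 13 libraries, 7771, also stayed within 1.5 times, but the numbers higher and lower moved further (6110 and 1661, and 6049 and 1528 with 10 libraries). The same held for the split by direction with limma on log2(TPM + 1) (7121 higher and 1029 lower) and log2(TPM + 0.1) (7266 and 1037). None of these applies composition factors, but the limma fits also change the test and the unit, so the cause was not separated for them. Totals moved further with an adjusted p under 0.01 (3682, of them 1676 higher and 2006 lower) and with at least a 2-fold change (2106, of them 1484 and 622), where the stricter threshold is the cause. With an estimated correlation 2 main lists were called in place of 16 in each set. For cell type and quality lists it was 0 in place of 6 and 5. The runs share the fits and differ only in how the correlation was set. Its estimates over the main lists were 0.0354 to 0.773 with 13 libraries and 0.0133 to 0.537 with 10, against the preset 0.01. With fry 8 cell type and quality lists were called with 10 libraries, in place of 5; the cause was not tested. The difference in spread between knock-in and wild-type libraries, 22.6, was not seen without knock-in 4, 5 and 6 (-2.60, exact permutation p = 0.419). Leaving out 1 library gave 18.3 to 25.5. Pparg passed the threshold with limma on log2(TPM + 1) (0.57, adjusted p = 0.0419) and log2(TPM + 0.1) (0.62, adjusted p = 0.0369), and with 10 libraries with library totals (0.73, adjusted p = 0.0438) and Xist as a covariate (0.59, adjusted p = 0.0432), while Ppara lost its call with log2(TPM + 1) (adjusted p = 0.0809) and log2(TPM + 0.1) (adjusted p = 0.0754). No pairing of the samples by replicate number was seen: same-numbered libraries correlated at -0.113 to 0.0845 in their deviations, and none matched its own number best. Knock-in deviations were taken from the mean of all knock-in libraries, among which 4, 5 and 6 stand apart, so a pairing could be missed. With a replicate block, without knock-in 7, 5162 genes (2575 higher, 2587 lower) and 15 main lists were called, the interferon response losing its call. Leaving out mitochondrially encoded genes had no genes to act on. Across wild-type libraries the relation of PPAR-gamma and adipocyte genes with the matrix score passed with the mean of log2 CPM (0.930, adjusted p = 0.0222); the cause was not tested. Depth limits genes near the filter on low counts, as the shallowest library had 14498336 reads.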

Other observations

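The tests of the metabolic lists and of other splits were fixed before their results were seen; the others here are values without a test of an explanation. Cell type lists not described above showed these counts with 13 libraries and then with 10. Of 10 cartilage and valve genes 6 were higher (6 higher and 0 lower adjusted over the list alone), and 5 of 9, led by Comp (log2 fold changes 3.19 and 3.48), a matrix protein of tendon and cartilage that fibroblasts also make, and Tnmd (4.62 and 4.83); the list was called at adjusted p = 0.00674 and 0.00085, and not with an estimated correlation (adjusted p = 0.301 and 0.265). Of 8 genes enriched in the left or right ventricle 4 were lower (0 higher and 4 lower adjusted over the list alone), and 6 lower and 1 higher, with Pcdh7 at -0.97 and -0.82 and Penk at -1.47 and -1.46 (adjusted p = 0.0254 and 0.0591; adjusted p = 0.301 and 0.265 with an estimated correlation), and with 10 libraries the list passed without wild type 5 (adjusted p = 0.0489) or knock-in 2 (adjusted p = 0.0498), with Xist as a covariate (adjusted p = 0.0253) and with fry (adjusted p = 7.39e-05). The deiodinase gene Dio2, listed with brown adipocytes, rose from 4.82 ± 3.01 to 53.2 ± 12.8 CPM (log2 fold changes 3.46 and 3.69), while 4 of the other members fell, Cox7a1 among them (adjusted p = 0.0526 and 0.213 for the list). With 13 libraries that list passed without any one of wild type 2 to 6 (adjusted p from 0.0296 to 0.0392) or knock-in 2 (adjusted p = 0.00915), and with 10 libraries without knock-in 2 (adjusted p = 0.0391). It also passed with DESeq2 size factors over 13 libraries (adjusted p = 0.0458) and with fry (adjusted p = 0.00490 and 0.00213).

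Lists with no call in either set were those of monocytes and neutrophils (adjusted p = 0.457 and 0.387), with Ccr2 at 1.02 and 1.21 and Csf3r at 1.35 and 1.32; B and plasma cells (0.766 and 0.772), with Jchain at 5.32, not tested with 10 libraries or without wild type 1 or knock-in 4, 5, 6 or 7, and Blk at 1.08 and 0.46, not called with 10; mast cells (0.512 and 0.654), with Mcpt4 at -1.11 and -0.93 and Cma1 at -0.80 and -0.55, Cma1 not called with 10; endothelium (0.477 and 0.663), with Car4 at -0.98 and -0.73 and Aqp1 at -0.67 and -0.47; mural cells (0.917 and 0.685), with Abcc9 at -0.97 and -0.72 and Mylk at 0.44 and 0.35; epicardium and mesothelium (0.917 and 0.896), with Krt18 at 5.00 and 0.67 and Krt8 at 6.79 and 0.05, neither called with 10; Schwann cells and neurons (0.917 and 0.387), with Dbh at -1.36 and -1.06 and Ncam1 at 0.85 and 1.20; and atrial cardiomyocytes (0.702 and 0.387), with Nr2f2 at 1.11 and 0.75 and Tbx5 at -0.89 and -0.61. Skeletal muscle (0.552 and 0.654) had Tnni2 at -1.69 and -1.64 and Ckm at -0.78 and -0.63, with a median of 0.51 over 13 libraries and a test that pointed down, and passed only with fry over 13 libraries (adjusted p = 0.0102). Erythrocyte (0.905 and 0.931), circadian clock (0.917 and 0.896, with Hlf at -0.76 and -0.46 and Bhlhe41 at 0.42 and 0.49) and sex-linked genes (0.961 and 0.84) were not called either. The sex-linked list joins Xist with Y-linked genes, which differ in opposite directions between the sexes, so its test cannot show a difference in sex. Its median log2 fold change was -0.51 and -1.38, with 0 of 5 members called. Immediate early genes were called with 13 libraries (adjusted p = 0.02; adjusted p = 0.846 with an estimated correlation), with Egr2 at 2.64 and 1.98 and Atf3 at 1.53 and 1.57, and not with 10 (adjusted p = 0.372). With fry they were called with 10 (adjusted p = 0.0365) and not with 13 (adjusted p = 0.0527).

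The third pattern is the fall of metabolic genes beside that of the sarcomere. A lower share of cardiomyocyte RNA would lower both alike if sarcomere genes kept their level within those cells. Only under that condition do the values argue against it as the whole cause. Sarcomere members did not move alike: with 10 libraries 14 of 24 fell and 10 were not called. In the 10 libraries the sarcomere list fell by 0.47 (log2, exact permutation p = 0.00476) on average, and relative to it the fatty acid oxidation list differed by -0.43 and the oxidative phosphorylation list by -0.44 (exact permutation p = 0.00476 for each, the smallest the 210 splits can give), below the lowest wild-type library in 4 of 4 knock-in libraries. With 13 libraries the relative differences were -0.37 and -0.40, in 7 of 7. A change of expression within cardiomyocytes that goes with the genotype remains a hypothesis that was not tested, and sarcomere genes may have changed within those cells too.

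Chance can be excluded for the counts of genes: 1 of 100 splits of the 13 libraries, the real one, gave as many as 6502 genes, with 2688 the most in another split, which set all 6 wild types and 1 knock-in against the rest, and 1 of 100 splits of the 10 libraries gave 6340, with 3554 the most in another, which set 4 wild types against the rest. All but a few other splits called no gene: 97 of 99 with 13 libraries and 96 of 99 with 10. With 100 splits the share cannot go below 1 of 100. Excluding chance does not make the 13-library count one of genotype alone. It holds 179 of the 498 genes at least 3 times higher in knock-in 4, 5 and 6 than in any other library. For the count of 16 main lists called with the preset correlation, 4 of 100 splits of the 13 libraries gave as many, with 16 the most in another split. Of the 99 other splits 3 reached it, with 2, 5 and 6 of the 7 knock-in libraries in the larger group. Such unlike shares carry part of the genotype contrast, and only 100 splits were drawn. The share therefore does not decide whether chance is excluded for that count. With the 10 libraries 19 of 100 splits gave 16 or more, with 17 the most in another. Some of these held 0 or 3 of the 4 knock-in libraries in the smaller group and carry part of that contrast too. A split with 2 of the 4 also gave 16, so chance cannot be excluded for that number.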
